A study of Arabidopsis thaliana with 14 samples.

How the data were processed

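Whole rosettes of Arabidopsis thaliana Col-0, 5 to 6 weeks old and grown in a 14 h photoperiod with a 10 h night, were sampled as the night was extended. Each sample held 3 rosettes, and about 10 µg of total RNA went into labelling for the Affymetrix ATH1 array. The 14 arrays covered 8 time points. There were 3 arrays at the end of the night (A, B and C), 2 each at 4 h (A and B), 8 h (A and B), 24 h (B and C) and 48 h (B and C) into the extended night, and 1 each at 2 h before the end of the night and at 2 h and 6 h into the extended night.

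The deposited values are log2 signal intensities per probe set after robust multi-array average (RMA) background correction, normalization and summarization by the authors; the RMA software and version are not given in the sources used here. Every array column was matched to a sample by its label. The labels do not say what each array's sample is beyond 3 rosettes. The p-values, apart from those of the slope, therefore measure only the spread between these samples. The number of arrays limits the precision: the 5 replicated time points leave 6 residual degrees of freedom.

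The table held 22810 probe sets, of which 64 Affymetrix controls were kept out of the tests and 22746 were tested with no filter on signal. The array annotation used here gave exactly 1 gene for 13513 probe sets, several for 503 and none for 8730, for 13355 different genes. Gene names came from the reference annotation TAIR10.1, which held the gene of 13436 of those probe sets and gave 1535 of the genes a symbol other than the locus; genes without a symbol appear by locus.

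Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 fit of the 14 arrays with the 8 time points as a factor and no replicate term. The median posterior standard deviation was 0.165 log2 units and the prior added 3.25 degrees of freedom. Each of 4 h, 8 h, 24 h and 48 h was compared with the end of the night, and 8 h with 4 h, 24 h with 8 h and 48 h with 24 h. The unreplicated times were compared with the end of the night in the same fit, where the lone array is assumed to vary like the replicated groups. A slope over hours was fitted to the 10 arrays from 2 h before to 8 h after the end of the night, and a moderated F-test covered any difference among the 8 time points. P-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. Errors after ± are limma standard errors. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

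The comparisons, tests, 23 gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each of 4 h, 8 h, 24 h and 48 h against the end of the night, the 5 largest called rises and 5 largest called falls among probe sets with 1 gene in which every array lay on one side of every end of night array, and up to 4 called members of each list. For the other comparisons of replicated times and the slope it took the 5 largest rises and falls called. Of 10 genes always to be named, only ATG8E had a probe set used here. Any other gene named was chosen after its values were seen.

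The 23 lists held 477 members, of which 104 were measured by a probe set with 1 gene; a gene with several such probe sets took the brightest. The 11 lists with at least 3 measured members were tested with limma's camera, with a preset correlation of 0.01 between genes, and, beside it, camera with an estimated correlation and fry. Lists with fewer measured members are described by their members in the comparisons with the end of the night, and 5 lists had none. A further 25 lists, of gene families and organelle genomes, were chosen by symbol after the array annotation was known and before changes were computed; for the mitochondrial genome, the values of 1 member had been seen. The first 23 and the further 25 lists were adjusted as separate families, where the plan had named all lists of a comparison together.

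The replicate letters were checked for pairing. Deviations from the time point means correlated at 0.17 to 0.58 (Pearson, across probe sets, which are not independent replicates) in the 16 pairs of arrays that shared a letter, all above 0.1, and at -0.58 to 0.365 in the 32 pairs with different letters. With 2 arrays at a time point the 2 deviations are exact opposites. Many values for different letters therefore mirror those for shared letters, some same-letter values repeat each other, and the pairs are not independent. The same-letter values could have taken either sign, and all were positive. On that ground the letters were taken to pair the samples, and a fit of the 11 lettered arrays with letter as a block was among the alternatives.

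Alternatives were another threshold (adjusted p under 0.01, or at least 2-fold), median centring or a second quantile normalization of the arrays, leaving out the dimmest 33.3% of probe sets, eBayes with trend and robust settings, array weights, the replicate block, fitting only the time points compared, and leaving out each array of the replicated times in turn. Leaving out both 48 h arrays, median centring for the lists, and simulated overlaps of lists cut to the observed sizes were chosen after seeing the data. The groups of at most 3 arrays were too small to test single arrays as outliers or to count other splits of the samples.

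The procedure was tested on simulated data with the same layout and 100 changed probe sets at each of 2 sizes. A log2 change of 1 was recovered in 89% of the probe sets at 4 h, 86% at 8 h, 84% at 24 h and 78% at 48 h, in 66% to 70% for the steps between replicated times, in 59% to 65% for the unreplicated times, in 79% for the slope and in 38% by the F-test. A change of 2 was recovered in 94% to 100%, with 5 to 14 false calls per comparison. When every member of each of the 11 testable lists was raised in turn by 1 log2 unit, 11 were called, with 0 calls in the 110 tests of the other lists. The simulated noise was independent between genes and between arrays, with no letter effect. These simulations therefore do not show how many false calls arise where members of a list are correlated or arrays share a letter.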

Results

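The series measured transcript levels in Arabidopsis rosettes kept in darkness past the normal end of the night, which addresses how expression changes as plants run short of the carbohydrate stored by day. After the RMA normalization the arrays had medians from 6.62 to 6.77 log2 units. Normalization makes arrays alike, so these medians do not compare their signal before it. Replicate arrays of one time point correlated at 0.975 to 0.993 across probe sets, lowest for the 48 h pair, in which the standard deviation of the difference was 0.46 log2 units against 0.25 for the 4 h pair. The 48 h B array had the lowest 25S rRNA control, at 8.98 log2 units against 13.66 on 48 h C and 11.05 to 13.78 on the others. Its 3' minus 5' difference was the largest on 1 of the 2 actin controls (2.02 against 0.90 to 1.71) and 1 of the 2 ubiquitin controls (1.08 against 0.62 to 0.99). On the others it was 2.44 against 1.87 to 2.74 for actin and 1.92 against 1.46 to 1.94 for ubiquitin, and it was within the range of the other arrays on both GAPDH controls. The times of 24 h and 48 h fell at the clock time of the end of the night, whereas 2 h to 8 h fell in the subjective day, so clock time and length of darkness differ together at those times.

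At 4 h into the extended night (n = 2 arrays, against n = 3 at the end of the night), transcripts for the breakdown of branched-chain amino acids were among the largest rises. IVD, isovaleryl-CoA dehydrogenase of leucine breakdown, rose by 4.78 ± 0.28 log2 units (27.4-fold, adjusted p = 1.12e-05), and MCCA, a subunit of methylcrotonyl-CoA carboxylase in the same pathway, rose by 4.23 ± 0.18. AT3G62550 rose by 4.33 ± 0.24, AT1G72060 by 4.29 ± 0.16 and AT1G25400 by 3.98 ± 0.41. The largest falls were in AT3G15310 (-4.05 ± 0.22, adjusted p = 8.01e-06), AT1G73600 (-3.39 ± 0.37), AT5G42760 (-3.15 ± 0.13), AT1G26790 (-3.07 ± 0.11) and AT3G28270 (-2.98 ± 0.29). The rule for naming these 10 genes required both 4 h arrays to lie on one side of all 3 end of night arrays.

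Among the amino acid catabolism genes, 9 of 13 measured members rose at 4 h and 0 fell (12 and 0 adjusted over the list alone), including MGL, methionine gamma-lyase (3.79 ± 0.28), and ETFQO, which passes electrons from these oxidations to ubiquinone (2.88 ± 0.33). The list's median was 2.2. Amino acid catabolism had adjusted p = 1.05e-12 by camera, and adjusted p = 0.0701 with an estimated correlation. Both measured sugar starvation markers rose, ATL8 by 3.56 ± 0.23 and AKINBETA1, a regulatory subunit of the energy-sensing kinase SnRK1, by 1.93 ± 0.20. Of 15 autophagy genes 7 rose and 1 fell, the same counts adjusted over the list alone, with ATG8E at 1.45 ± 0.13 and APG8A at 0.94 ± 0.15. Autophagy had a median of 0.39 and adjusted p = 3.37e-04 by camera, and adjusted p = 0.249 with an estimated correlation. Among leaf senescence genes 3 of 7 rose (5 adjusted over the list alone), led by WRKY22 (2.12 ± 0.15), with WRKY53 (1.33 ± 0.28, a call lost without 4 h array A, adjusted p = 0.0998) and the ethylene-signalling factor EIN3 (1.11 ± 0.14). Leaf senescence had adjusted p = 0.00131 by camera, and adjusted p = 0.0701 with an estimated correlation. Of 3 genes of fatty acid beta-oxidation and the glyoxylate cycle, 1 rose (2 adjusted over the list alone), SDP1, a triacylglycerol lipase, by 2.48 ± 0.22. Fatty acid beta-oxidation and the glyoxylate cycle had adjusted p = 0.00922 by camera, and adjusted p = 0.128 with an estimated correlation.

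Ribosome biogenesis genes fell in 4 of 15 cases at 4 h, also 4 adjusted over the list alone, with AT3G15460, a BRX1 homologue, at -1.62 ± 0.16 and AT2G40360, a BOP1 homologue, at -0.91 ± 0.11. Ribosome biogenesis had a median of -0.23 and adjusted p = 0.0176 by camera, and adjusted p = 0.249 with an estimated correlation, and 0.11 without end of night array A. Of 13 cytosolic ribosomal proteins 1 fell (0 adjusted over the list alone), and the list passed camera only when letters were blocked, after a second quantile normalization or without end of night array B or C (adjusted p = 0.0559 without these, 0.0119 with the block, 0.0477 after quantile normalization, 0.0479 without array B and 0.017 without array C). In photosynthesis LHCB4.3, a light-harvesting protein, fell by 1.32 ± 0.19, 1 of 2 falls among 10 genes (2 adjusted over the list alone; list adjusted p = 0.463), and in tetrapyrrole synthesis CHLI2, of magnesium chelatase, fell by 0.56 ± 0.10, 1 of 2 among 6 (2 adjusted over the list alone; list adjusted p = 0.363). Of the 2 starch degradation genes PWD, phosphoglucan water dikinase, fell (-1.33 ± 0.10) and DPE1 was at -0.65 ± 0.29 (adjusted p = 0.18; 2 falls adjusted over the list alone). Also down were DFR (-1.66 ± 0.35, and -0.997 without 4 h array B) and UF3GT (-0.99 ± 0.15) of anthocyanin synthesis and PRL, the replication factor MCM7 (-1.04 ± 0.20). In cell wall growth XTH16 (-1.47 ± 0.25) and EXPA15 (-0.62 ± 0.17) fell, 2 of 5 genes and 2 adjusted over the list alone (list adjusted p = 0.117). GI, of the circadian clock, rose by 0.72 ± 0.20. Several calls at 4 h were lost when 1 of the 4 h arrays was left out, though the changes kept their direction. Without array A the change was -1.263 for XTH16, -0.994 for PRL, -0.583 for EXPA15 and -0.338 for the SBPASE of photosynthesis. Without array B it was -0.997 for DFR, 0.606 for GI and -0.494 for the GSA1 of tetrapyrrole synthesis. Calls were also lost for AT5G08180 (-0.58) and AT1G52930 (-0.642) of ribosome biogenesis without array B. The same held for ATG8H (0.845) and ATG8F (0.685) of autophagy without array B, and for the ribosomal protein AT2G01250 (-0.32) without array A. For EXPA15, GI, SBPASE, AT5G08180, AT1G52930 and AT2G01250 the call was lost whichever 4 h array was left out. For SBPASE, AT5G08180 and AT2G01250 it was also lost without any 1 of the end of night arrays. The same held for EXPA15 without end of night array A or C and for GI without C. SBPASE and AT2G01250 further lost their calls with median centring, with trend and robust settings and without the dimmest probe sets.

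Across the array, 3700 of 22746 probe sets were called at 4 h, 1703 up and 1997 down, with 695 of the rises and 603 of the falls at least 2-fold. The count was 5960 with letters as a block, 1759 without 4 h array A and 1901 without 4 h array B.

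**Figure D1:**
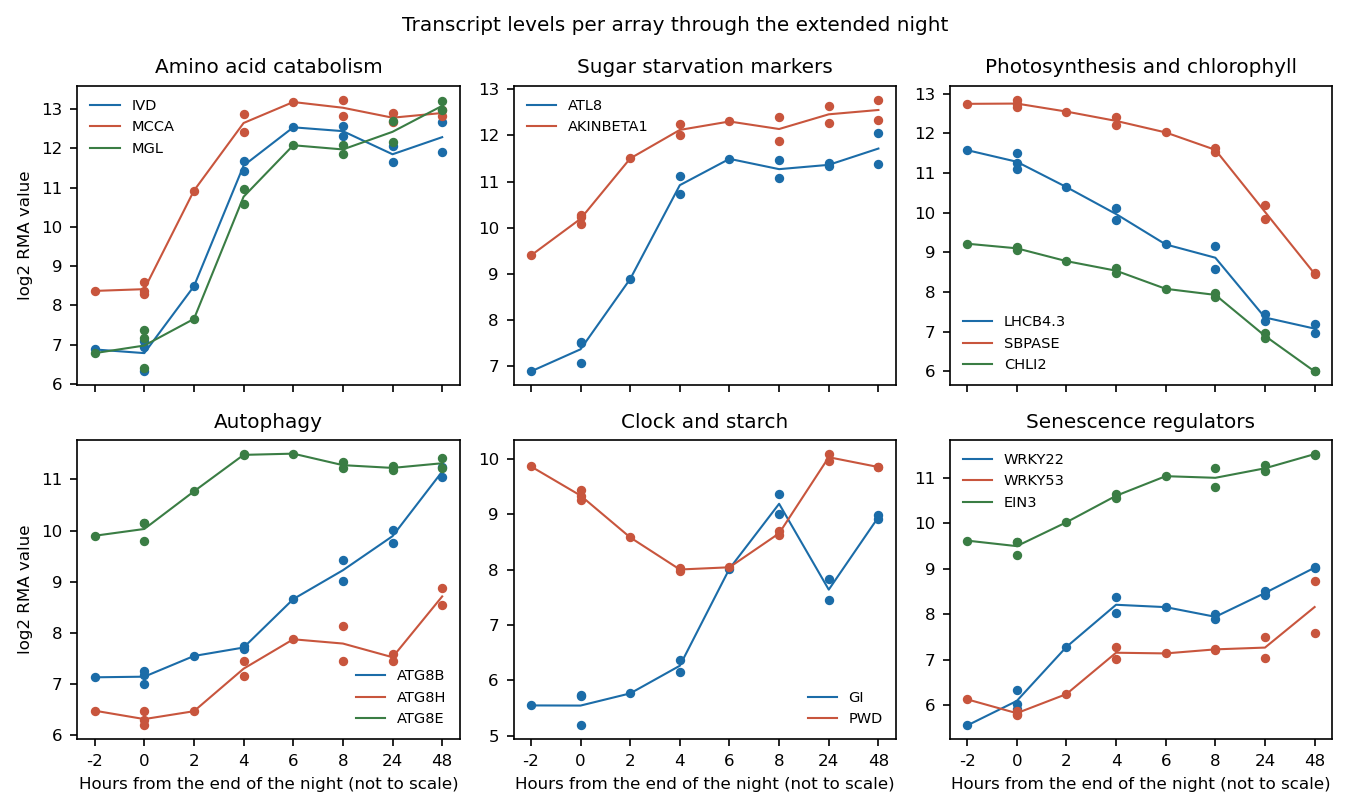
Log2 signal of named genes against hours from the end of the night, not to scale, with 1 point per array and lines through the time point means. IVD, MGL and ATG8B lay higher, and SBPASE and CHLI2 lower, on both 48 h arrays than on the 3 end of night arrays.

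At 8 h (n = 2 against n = 3) transcripts of leucine and methionine breakdown were among the largest rises against the end of the night. IVD rose by 5.65 ± 0.28 (50.3-fold, adjusted p = 1.62e-06), MGL by 4.99 ± 0.28 and MCCA by 4.62 ± 0.18. The other 2 of the 5 largest rises were AT3G62550 (5.93 ± 0.24) and AT1G72060 (5.28 ± 0.16). HYH, a light-signalling bZIP factor related to HY5, fell by 4.58 ± 0.26 (adjusted p = 3.27e-06) and GSTU20, a glutathione S-transferase, fell by 3.87 ± 0.23, beside AT3G15310 (-4.66 ± 0.22), AT1G73600 (-4.03 ± 0.37) and AT4G21870 (-4.02 ± 0.19).

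Amino acid catabolism genes rose in 11 of 13 cases at 8 h and fell in 0 (11 and 1 adjusted over the list alone). AT4G33150, the bifunctional enzyme of lysine breakdown, rose by 4.58 ± 0.34. Amino acid catabolism had a median of 2.91 and adjusted p = 8.64e-10 by camera, and adjusted p = 0.154 with an estimated correlation. Autophagy genes rose in 8 of 15 cases, the same adjusted over the list alone, with ATG8B at 2.09 ± 0.15, APG8A at 1.72 ± 0.15 and ATG8H at 1.48 ± 0.21. Autophagy had adjusted p = 1.19e-05 by camera, and adjusted p = 0.191 with an estimated correlation. ATL8 (3.91 ± 0.23) and AKINBETA1 (1.95 ± 0.20) rose, as did SDP1 (2.07 ± 0.22) and AIM1 (1.01 ± 0.12), 2 of the 3 beta-oxidation and glyoxylate genes and 2 adjusted over the list alone. Fatty acid beta-oxidation and the glyoxylate cycle had adjusted p = 0.017 by camera, and adjusted p = 0.154 with an estimated correlation. Leaf senescence genes rose in 4 of 7 cases, also 4 adjusted over the list alone, with WRKY22 at 1.85 ± 0.15, EIN3 at 1.5 ± 0.14 and WRKY53 at 1.40 ± 0.28. The other rise, of SAG101 (0.62 ± 0.20), lost its call without any 1 of the end of night arrays and from the 2 time points alone. It was also lost without 8 h array A, where the change was 0.3. Leaf senescence had adjusted p = 0.017 by camera, and adjusted p = 0.154 with an estimated correlation. GI rose by 3.64 ± 0.20.

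Photosynthesis genes fell in 3 of 10 cases at 8 h, also 3 adjusted over the list alone, with LHCB4.3 at -2.42 ± 0.19 and SBPASE, a Calvin cycle enzyme, at -1.17 ± 0.13; the list's camera test gave adjusted p = 0.0734, and 0.0456 with both 48 h arrays left out. In tetrapyrrole synthesis CHLI2 (-1.17 ± 0.10) and GSA1 (-1.20 ± 0.16) fell while PORB, a protochlorophyllide oxidoreductase, rose by 1.37 ± 0.20, for 3 falls and 1 rise among 6, the same adjusted over the list alone. That list's call (adjusted p = 0.0412; adjusted p = 0.191 with an estimated correlation) was lost without end of night array A (0.0727) or B (0.0648) or 8 h array B (0.0953). In tetrapyrrole synthesis the fall of HEMB1 (-0.60 ± 0.19) lost its call with median centring, a second quantile normalization and the 2 time points alone. It was also lost without end of night array A or B and without 8 h array A (-0.421). In photosynthesis the fall of PRK (-0.76 ± 0.17) lost its call without 8 h array B (-0.657). Of 13 cytosolic ribosomal proteins 4 fell, also 4 adjusted over the list alone, with AT5G02870, RPL4D, at -0.71 ± 0.14. The calls of PGY1 and AT2G19730 were lost with median centring (adjusted p = 0.0767 and 0.0993). They were also lost without 8 h array A (-0.283 and -0.34). The list of cytosolic ribosomal proteins had adjusted p = 0.0277 by camera, and adjusted p = 0.205 with an estimated correlation, 0.0837 without end of night array A and 0.119 without 8 h array B. Ribosome biogenesis genes fell in 3 of 15 cases and rose in 1, the same adjusted over the list alone (list adjusted p = 0.149, though the list was called without 8 h array A). The rise, of AT3G22660, lost its call without 8 h array A (0.679) or B (0.7). The fall of AT1G52930 lost its call without 8 h array B (-0.404) and without end of night array A or B. APL3 of starch synthesis fell by 1.15 ± 0.17, 1 of 2 falls among 3, also 2 adjusted over the list alone (list adjusted p = 0.0899, and 0.0397 without end of night array C). The other fall, of SBE2.2, lost its call without end of night array A or B (adjusted p = 0.0748 and 0.083). It was also lost without 8 h array A (-0.773) or B (-0.8). Of the 2 starch degradation genes PWD fell by 0.68 ± 0.10. DPE1, a disproportionating enzyme, rose by 1.13 ± 0.29, a call lost without 8 h array B (0.958). XTH16 fell by 2.05 ± 0.25, 1 of 2 falls among 5 cell wall growth genes and 2 adjusted over the list alone. The other, EXPA15 (-0.71 ± 0.17), lost its call without 8 h array B (-0.594). The list of cell wall growth had adjusted p = 0.0604 by camera, 0.0317 with median centring and 0.041 with both 48 h arrays left out. It was also called without 8 h array A. DFR (-2.94 ± 0.35), UF3GT (-0.92 ± 0.15) and PRL (-1.41 ± 0.20) fell.

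At 8 h 6310 probe sets were called, 2893 up and 3417 down, of which 1208 and 1484 were at least 2-fold. Median centring turned the split, to 3423 up and 2972 down.

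By 24 h (n = 2 against n = 3), at the clock time of the end of the night, ATSPS4F fell most among the probe sets eligible for naming. ATSPS4F, a sucrose-phosphate synthase, fell by 4.76 ± 0.23 (27.2-fold, adjusted p = 1.03e-06). LrgB, the plastid glycolate and glycerate transporter, fell by 4.64 ± 0.14. AT1G06830 (-4.47 ± 0.13), AT3G15310 (-4.45 ± 0.22) and GSTU20 (-4.43 ± 0.23) completed the 5 largest falls. MGL rose by 5.44 ± 0.28 (43.5-fold, adjusted p = 1.39e-06), AT1G62510 by 5.16 ± 0.26, IVD by 5.07 ± 0.28, AT1G72060 by 5.06 ± 0.16 and AT5G39520 by 5.04 ± 0.24.

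Photosynthesis genes fell in 7 of 10 cases at 24 h (8 adjusted over the list alone), with LHCB4.3 at -3.93 ± 0.19, SBPASE at -2.73 ± 0.13 and PRK, phosphoribulokinase, at -1.21 ± 0.17. Photosynthesis had a median of -0.53 and adjusted p = 5.31e-05 by camera, and adjusted p = 0.0475 with an estimated correlation. Tetrapyrrole synthesis fell in 5 of 6 genes, also 5 adjusted over the list alone, with CHLI2 at -2.21 ± 0.10, GSA1 at -1.78 ± 0.16 and HEMB1 at -1.53 ± 0.19. Tetrapyrrole synthesis had a median of -1.18 and adjusted p = 2.17e-04 by camera, and adjusted p = 0.0892 with an estimated correlation. All 3 measured starch synthesis genes fell, also adjusted over the list alone, with APL3 at -1.26 ± 0.17 and SBE2.2 at -1.19 ± 0.23. The third, APL4, lost its call without 24 h array C (adjusted p = 0.103). Starch synthesis had adjusted p = 0.011 by camera, and adjusted p = 0.144 with an estimated correlation. Amino acid catabolism genes rose in 10 of 13 cases and fell in 1 (11 and 1 adjusted over the list alone). Amino acid catabolism had a median of 2.51 and adjusted p = 1.08e-06 by camera, and adjusted p = 0.127 with an estimated correlation. Autophagy genes rose in 11 of 15, the same adjusted over the list alone, led by ATG8B (2.75 ± 0.15; list adjusted p = 3.49e-06, and adjusted p = 0.134 with an estimated correlation). Leaf senescence genes rose in 4 of 7, also 4 adjusted over the list alone, with WRKY22 at 2.38 ± 0.15, EIN3 at 1.71 ± 0.14 and WRKY53 at 1.44 ± 0.28. Leaf senescence had adjusted p = 0.011 by camera, and adjusted p = 0.105 with an estimated correlation.

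ATL8 (4.00 ± 0.23) and AKINBETA1 (2.27 ± 0.20) were up at 24 h, and GI rose by 2.09 ± 0.20. PWD, down at 4 h and 8 h, rose by 0.69 ± 0.10, while DPE1 was at 0.50 ± 0.29 (adjusted p = 0.238). DFR (-3.60 ± 0.35), UF3GT (-0.91 ± 0.15) and PRL (-2.09 ± 0.20) fell. SDP1 (1.59 ± 0.22) and AIM1 (0.95 ± 0.12) rose, 2 of 3 in the list of fatty acid beta-oxidation and glyoxylate cycle and 2 adjusted over the list alone; its call (adjusted p = 0.0479; adjusted p = 0.144 with an estimated correlation) was lost with median centring (0.0598), with both 48 h arrays left out (0.0686) and without end of night array B (0.0504) or C (0.056) or 24 h array B (0.15). Of 13 cytosolic ribosomal proteins 4 fell, with AT2G01250, RPL7B, at -0.98 ± 0.10, and of 15 ribosome biogenesis genes 3 fell and 1 rose, all the same adjusted over the list alone (list adjusted p = 0.108 and 0.274). In ribosome biogenesis the rise of AT5G15550 and the fall of AT5G08180 lost their calls without 24 h array B (0.412 and -0.571). The ribosomal protein AT5G07090 lost its call without 24 h array C (-0.658). EXPA15 fell by 0.87 ± 0.17, 1 of 5 cell wall genes and 2 adjusted over the list alone (list adjusted p = 0.506). At 24 h 7426 probe sets were called, 3524 up and 3902 down, with 1538 and 1836 of them at least 2-fold. With median centring rises outnumbered falls, at 4138 against 3461.

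At 48 h (n = 2 against n = 3) LrgB, the plastid transporter, fell most among the probe sets eligible for naming. Its fall was 5.84 ± 0.14 (57.2-fold, adjusted p = 2.68e-08). CaS, a thylakoid calcium sensor, fell by 5.45 ± 0.18, and AT3G48420 (-5.45 ± 0.20), GSTU20 (-5.05 ± 0.23) and AT1G06830 (-4.92 ± 0.13) followed. The largest rises among the eligible probe sets were in AT1G19530 (6.26 ± 0.45), MGL (6.11 ± 0.28, 68.8-fold, adjusted p = 3.41e-07), AT5G39520 (5.79 ± 0.24), AT4G33150 of lysine breakdown (5.75 ± 0.34) and HIS1-3, a linker histone (5.52 ± 0.11).

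Photosynthesis genes fell in 9 of 10 cases at 48 h (10 adjusted over the list alone), with SBPASE at -4.29 ± 0.13, LHCB4.3 at -4.21 ± 0.19, RCA, Rubisco activase, at -3.01 ± 0.48 (-2.001 without 48 h array B) and PRK at -2.80 ± 0.17. Photosynthesis had a median of -1.36 and adjusted p = 1.70e-07 by camera, and adjusted p = 0.014 with an estimated correlation. Tetrapyrrole synthesis genes fell in 5 of 6 cases, also 5 adjusted over the list alone, with CHLI2 at -3.10 ± 0.10 and CHLM at -1.35 ± 0.10. Tetrapyrrole synthesis had a median of -1.53 and adjusted p = 6.32e-05 by camera, and adjusted p = 0.0461 with an estimated correlation. Autophagy genes rose in 13 of 15, the same adjusted over the list alone, with ATG8B at 4.02 ± 0.15 and ATG8H at 2.40 ± 0.21. Autophagy had a median of 0.95 and adjusted p = 5.20e-07 by camera, and adjusted p = 0.112 with an estimated correlation. Amino acid catabolism genes rose in 11 of 13 and fell in 1, the same adjusted over the list alone. Amino acid catabolism had a median of 3.26 and adjusted p = 1.70e-07 by camera, and adjusted p = 0.106 with an estimated correlation. Leaf senescence genes rose in 5 of 7, also 5 adjusted over the list alone, with WRKY22 at 2.93 ± 0.15, WRKY53 at 2.33 ± 0.28, EIN3 at 2.02 ± 0.14 and WRKY6 at 1.52 ± 0.28. Leaf senescence had adjusted p = 0.00141 by camera, and adjusted p = 0.0461 with an estimated correlation.

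ATL8 (4.36 ± 0.23), AKINBETA1 (2.36 ± 0.20), GI (3.40 ± 0.20), SDP1 (1.81 ± 0.22) and PWD (0.52 ± 0.10) were up at 48 h, and DFR (-3.17 ± 0.35), UF3GT (-1.02 ± 0.15) and PRL (-2.37 ± 0.20) were down. The beta-oxidation list, with 2 of 3 up and 2 adjusted over the list alone, gave adjusted p = 0.0865. In starch synthesis APL3 fell by 1.36 ± 0.17, 1 of 2 falls among 3 and 2 adjusted over the list alone. Starch synthesis had adjusted p = 0.0338 by camera, and adjusted p = 0.223 with an estimated correlation, 0.0516 without end of night array A and 0.0834 without 48 h array C. EXPA8, an expansin, fell by 2.3 ± 0.40, 1 of 3 falls among 5 cell wall growth genes and 3 adjusted over the list alone. The list of cell wall growth had adjusted p = 0.0226 by camera, and adjusted p = 0.278 with an estimated correlation, and 0.115 without 48 h array B. Of the 13 cytosolic ribosomal proteins 4 fell, also 4 adjusted over the list alone, with AT2G01250 at -1.38 ± 0.10; the list's call (adjusted p = 0.0338; adjusted p = 0.223 with an estimated correlation) was lost with letters as a block (0.0692) and without end of night array A (0.076) or 48 h array B (0.095). Ribosome biogenesis genes fell in 2 of 15 cases and rose in 1, the same adjusted over the list alone (list adjusted p = 0.58). AT3G10040, HRA1 of the hypoxia response, fell by 0.42 ± 0.11. Its call was lost with median centring (adjusted p = 0.0518), with array weights (0.0546) and without 48 h array C (-0.394). Its values, 4.56 to 5.11, lay below the lower quartile of every array. AT5G52660, the clock factor RVE6, rose by 0.40 ± 0.13, a call lost without 48 h array B (0.423) or C (0.368). It was also lost without end of night array B (adjusted p = 0.12) or C (0.106). The same held with trend and robust settings (adjusted p = 0.0747), array weights (0.13) and the 2 time points alone (0.119). At 4 h, 8 h and 24 h AT3G10040 was at -0.20 ± 0.11, -0.17 ± 0.11 and -0.11 ± 0.11, AT5G52660 at 0.02 ± 0.13, 0.26 ± 0.13 and 0.18 ± 0.13, and at 48 h DPE1 was at 0.32 ± 0.29, none of them called. Of the 3 root markers and the guard cell gene FAMA, 0 were called at 4 h, 8 h, 24 h or 48 h, before or adjusted over the list alone, and camera on the root markers gave adjusted p from 0.599 to 0.786. At 48 h 9287 probe sets were called, 4664 up and 4623 down, with 2283 and 2490 of them at least 2-fold. Falls were also the more numerous at adjusted p under 0.01 (3526 against 3455), without the dimmest probe sets (4326 against 4133), with array weights (4070 against 4048), from the 2 time points alone (4050 against 3983) and without end of night array A (4174 against 4134), B (4228 against 4209) or C (4403 against 4314). Median centring moved the split the other way, to 5538 up and 4119 down.

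**Figure D2:**
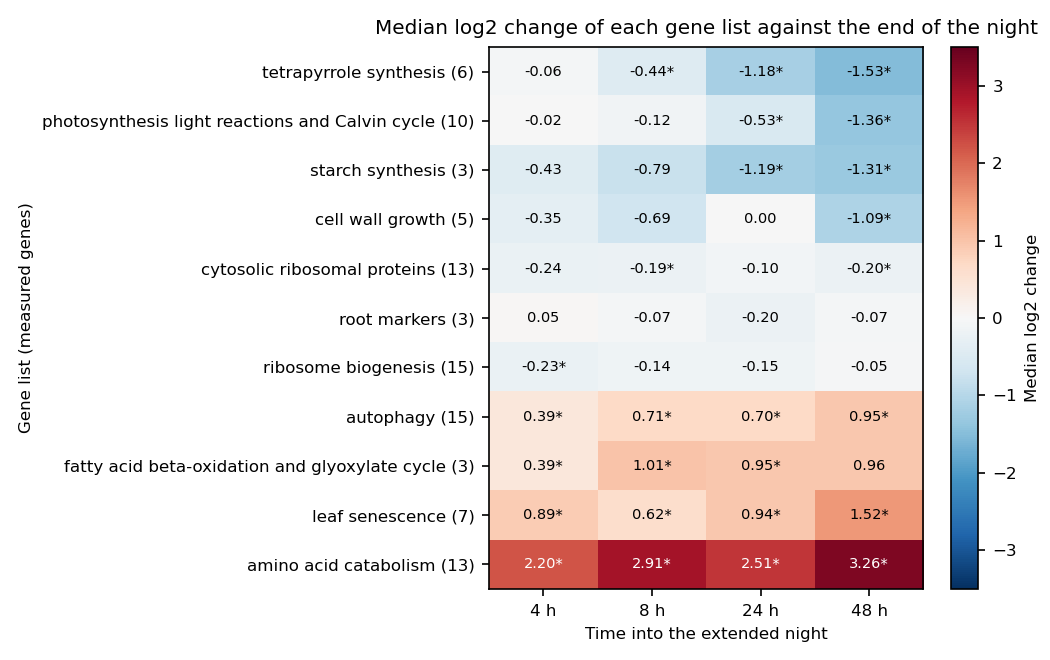
Median log2 change of the measured members of each tested gene list (vertical axis, number measured in brackets) at 4 h, 8 h, 24 h and 48 h against the end of the night (horizontal axis), with stars where camera gave an adjusted p under 0.05. Amino acid catabolism reached a median of 3.26 at 48 h and photosynthesis -1.36.

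Between 4 h and 8 h (n = 2 each), within the subjective day, AT1G56300 rose by 4.35 ± 0.27 (adjusted p = 2.82e-04), AT2G39920 by 3.42 ± 0.41 and AT3G15440 by 3.12 ± 0.23. HYH fell by 3.03 ± 0.28 (adjusted p = 0.00114) and AT3G57020 fell by 2.51 ± 0.25. Amino acid catabolism genes rose in 2 of 13 cases (7 adjusted over the list alone) and autophagy genes in 3 of 15 (4 adjusted over the list alone), with adjusted p = 3.42e-04 and 0.00284, or adjusted p = 0.359 and 0.438 with an estimated correlation. Photosynthesis genes fell in 2 of 10 cases, also 2 adjusted over the list alone. Photosynthesis had adjusted p = 0.00815 by camera, and adjusted p = 0.245 with an estimated correlation. Tetrapyrrole synthesis had 1 fall and 1 rise among 6 (4 and 1 adjusted over the list alone). Tetrapyrrole synthesis had adjusted p = 0.00815 by camera, and adjusted p = 0.259 with an estimated correlation. Ribosome biogenesis, with 0 members called, also 0 adjusted over the list alone, had adjusted p = 0.249, and 0.0221 without 8 h array B. In all 874 probe sets were called, 377 up and 497 down, and 2459 with letters as a block. Falls did not outnumber rises with median centring (443 up and 421 down) or without 4 h array A (94 up and 91 down). The count was 1391 with array weights, 185 without 4 h array A, 305 without 4 h array B, 397 without 8 h array A and 263 without 8 h array B.

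From 8 h to 24 h (n = 2 each) the plant passed from the subjective day to the clock time of the end of the night. COR27, a cold- and clock-regulated gene, rose by 3.59 ± 0.26 (adjusted p = 3.05e-04), HIS1-3 by 2.54 ± 0.12 and AT3G20340 by 2.32 ± 0.25. AT1G70820 fell by 2.79 ± 0.21 (adjusted p = 3.97e-04), AT1G22430 fell by 2.33 ± 0.17 and AT1G52510 fell by 2.29 ± 0.15. RR16, a type A response regulator, rose by 2.53 ± 0.40 and LTI30, a dehydrin, fell by 2.40 ± 0.48, but the first call was lost without 8 h array A (adjusted p = 0.0742), 24 h array B (0.0746) or 24 h array C (0.0852) and the second without any 1 of the 4 arrays (adjusted p = 0.0849 to 0.178). Photosynthesis genes fell in 3 of 10 cases (6 adjusted over the list alone). Photosynthesis had a median of -0.50 and adjusted p = 1.19e-07 by camera, and adjusted p = 0.0119 with an estimated correlation. Tetrapyrrole synthesis genes fell in 4 of 6 (5 adjusted over the list alone). Tetrapyrrole synthesis had a median of -0.75 and adjusted p = 1.57e-07 by camera, and adjusted p = 0.0192 with an estimated correlation. The amino acid catabolism list, with a median of -0.20 and 0 members called, gave adjusted p = 0.0733, and 0.0298 with both 48 h arrays left out, 0.0217 without 8 h array B and 0.0244 without 24 h array B. For cell wall growth, with 1 of 5 up and 1 adjusted over the list alone, these were 0.0733, 0.0298 with both 48 h arrays left out and 0.0244 without 24 h array B. In all 736 probe sets were called, 306 up and 430 down, and 1523 with letters as a block, 764 up and 759 down. The count was 273 from these 2 time points alone, 261 without 8 h array A, 243 without 8 h array B, 230 without 24 h array B and 157 without 24 h array C.

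From 24 h to 48 h (n = 2 each), at one clock time, CHI (AT2G43570), a chitinase, rose by 2.75 ± 0.23 (adjusted p = 5.99e-04) and AT1G68620 by 2.86 ± 0.38, while AT4G24780 fell by 2.43 ± 0.22 and CaS fell by 2.28 ± 0.20 (adjusted p = 7.25e-04). AT4G16260 rose by 3.21 ± 0.54 and EXPA8 fell by 2.3 ± 0.43, but neither call held without 24 h array B (adjusted p = 0.0815 and 0.0757) or C (0.065 and 0.133). Photosynthesis genes fell in 4 of 10 cases (7 adjusted over the list alone; median -0.64, adjusted p = 2.13e-10, and adjusted p = 0.00506 with an estimated correlation), and tetrapyrrole synthesis genes in 3 of 6, also 3 adjusted over the list alone. Tetrapyrrole synthesis had adjusted p = 0.00219 by camera, and adjusted p = 0.128 with an estimated correlation. Amino acid catabolism genes rose in 3 of 13 (4 adjusted over the list alone), autophagy genes in 2 of 15, also 2 adjusted over the list alone, and leaf senescence genes in 1 of 7 (3 adjusted over the list alone), with adjusted p = 1.69e-05, 1.95e-04 and 8.99e-04, or adjusted p = 0.194, 0.203 and 0.0596 with an estimated correlation. Cell wall growth fell in 1 of 5 genes (4 adjusted over the list alone; adjusted p = 8.64e-04, adjusted p = 0.203 with an estimated correlation, and 0.0608 without 48 h array B). Of the cytosolic ribosomal proteins 0 were called, also 0 adjusted over the list alone, and the list's call (adjusted p = 0.0441; adjusted p = 0.274 with an estimated correlation) was lost without 24 h array B (0.198), 48 h array B (0.21) or 48 h array C (0.0759). In all 1144 probe sets were called, 565 up and 579 down, and 2972 with letters as a block. Which direction had more calls turned with at least 2-fold change (295 up and 268 down), median centring (596 and 537), trend and robust settings (552 and 543) and without 24 h array C (179 and 167), 48 h array B (479 and 402) or 48 h array C (929 and 810). The count was 645 with array weights, 364 without 24 h array B, 346 without 24 h array C and 1739 without 48 h array C. From these 2 time points alone 2 probe sets were called, and none of the genes named here.

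The times of 2 h, 6 h and -2 h rest on 1 array each, which adds no spread of its own, so their errors and p-values come from the replicated times. The largest called rises at 2 h were in probe sets without a single gene, up to 4.43 log2 units. Among those with 1 gene AT2G20670 rose most, by 2.64. At 2 h MCCA was higher by 2.51 ± 0.23 (adjusted p = 0.00238), AT1G72060 by 2.14 ± 0.20 (adjusted p = 0.00238) and WRKY22 by 1.19 ± 0.19 (adjusted p = 0.0348), while PWD (AT5G26570) was lower by 0.76 ± 0.13 (adjusted p = 0.0446). In all 99 probe sets were called at 2 h, 89 up and 10 down. At 4 h 89 and 10 of these were also called in the same direction, and at 8 h 85 and 10. All share the end of night arrays, and in 20 simulated sets without effects lists of these sizes shared on average 36.8 up and 4.65 down (at most 46 and 8) with 4 h and 46.5 and 6.5 (at most 55 and 10) with 8 h, above the values with simulated letters. The single array at 6 h gave 4091 calls, 1885 up and 2206 down, a split that median centring turned to 2172 up and 1897 down. Before the end of the night, at -2 h, 2 probe sets were called, AT1G26790 (-2.36 ± 0.13, adjusted p = 4.26e-04) and AT5G19120 (-1.45 ± 0.15, adjusted p = 0.039), both lower than at the end of the night, against 946 at an unadjusted p under 0.05. The count was 1 after a second quantile normalization, 0 without the dimmest probe sets, 8 with array weights and 13 with trend and robust settings.

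Over the 10 arrays from 2 h before to 8 h after the end of the night, IVD rose by 0.71 ± 0.08 log2 units per hour (adjusted p = 4.33e-05), AT1G72060 by 0.68 ± 0.06 and MGL by 0.64 ± 0.07. AT3G15310 fell by 0.56 ± 0.07 per hour, AT1G73600 fell by 0.54 ± 0.05 and HYH fell by 0.52 ± 0.05 (adjusted p = 2.96e-05). These slopes are averages over the span and not steady rates. IVD was at 6.88 at -2 h, 6.79 at the end of the night, 11.56 at 4 h and 12.44 at 8 h. The errors and p-values of the slope therefore also take in departures from a straight line. The slope was called in 8236 probe sets, 3747 up and 4489 down; after median centring the split turned, with 4872 up and 3813 down of 8685. Any change among the 8 time points was called in 8070 probe sets.

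Calls of successive times overlapped. At 4 h and 8 h, 3282 probe sets were called in one direction, 1456 up and 1826 down, where independent lists of these sizes would share 217 up and 300 down. A further 11 were called in opposite directions. At 8 h and 24 h the shared calls were 2326 up and 2844 down (independent lists, 448 and 586) with 17 opposite, and at 24 h and 48 h they were 3095 up and 3498 down (723 and 793) with 13 opposite. These comparisons share the 3 end of night arrays, too few to leave 2 in each part of a split, so part of the excess may come from them. In 20 simulated sets without effects, lists cut to the observed sizes shared on average 643 up and 792 down at 4 h and 8 h, 1063 and 1296 at 8 h and 24 h, and 1498 and 1608 at 24 h and 48 h. With a simulated letter effect of 0.522 of the variance, the mean correlation between times of the differences between letters, these became 722 and 897, then 835 and 1028, then 1694 and 1805. The highest of the 20 sets with letters were 764 and 939, 865 and 1074, and 1732 and 1857. Calls in one direction at all of 4 h, 8 h, 24 h and 48 h numbered 1210 up and 1560 down, of 10824 called at 1 or more of these times.

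**Figure D3:**
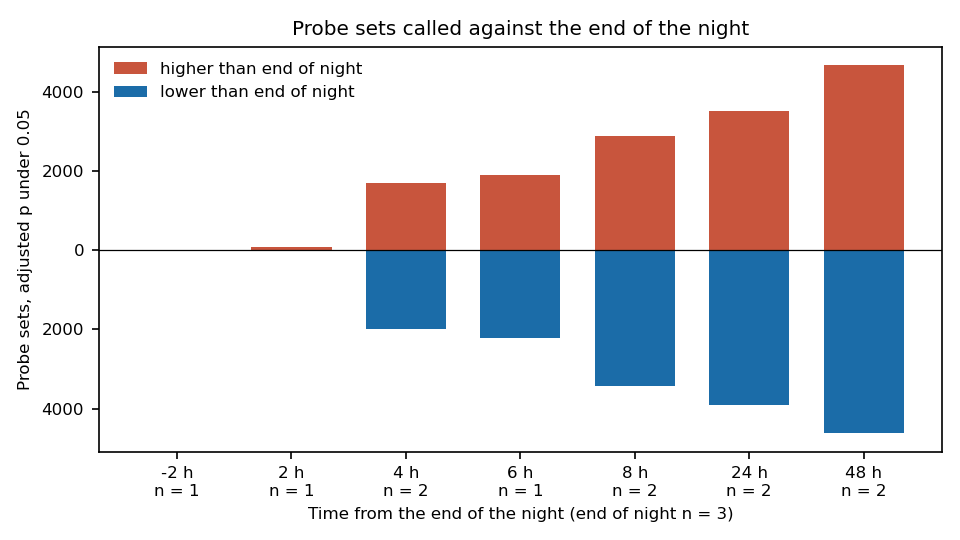
Number of probe sets called higher (bars above 0) and lower (bars below 0) than at the end of the night at each time, with limma at an adjusted p under 0.05 and the number of arrays under each time. At the replicated times the counts ran from 3700 at 4 h to 9287 at 48 h.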

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

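Of the tests in this part, those of clock time and of the replicate letters were chosen after the result was seen. PWD (AT5G26570), phosphoglucan water dikinase of starch breakdown, and AT1G70820 came up for a closer look because their changes at 8 h and 24 h went in opposite directions and differed by a test of the difference itself. PWD was -0.68 at 8 h and 0.69 at 24 h, a difference of 1.37 ± 0.11 (adjusted p = 4.50e-04). AT1G70820 was 1.33 at 8 h and -1.46 at 24 h, a difference of -2.79 ± 0.21 (adjusted p = 3.97e-04).

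These were 2 of 17 probe sets called in opposite directions at 8 h and 24 h, and the difference was called in all 17. Of the 17, 8 rose and then fell and 9 fell and then rose. With letters as a block 55 were called in opposite directions, these 17 among them. If the clock time of harvest lay behind them, most should keep the 24 h sign at 48 h, which shares its clock time: 94.1% did, 16 of 17, but so did 98.7% of all 7426 probe sets called at 24 h, so this decides nothing. A constant shift between the replicate letters, which differ at the 2 times, is argued against by the fit with letter as a block, where the 24 h minus 8 h change was 0.851 to 1.08 times that without it (median 0.985) in these 17. A letter effect that itself varied with time was not tested. An effect of clock time and a response to darkness that turned between 8 h and 24 h cannot be told apart, since both would keep their sign at 48 h and the comparisons share the end of night arrays.

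There were 6310 probe sets called at 8 h. Clock time alone would bring their values back toward 0 at 24 h if the clock kept its period. The median ratio of the 24 h change to the 8 h change was 1.02 (quartiles 0.751 and 1.29). The ratio argues against clock time as the whole cause only under that condition, which was not tested. Of the 2 measured clock genes GI was still up by 2.09 at 24 h. The other, AT5G52660, was at 7.61 and 7.62 on the 24 h arrays, within the end of night range of 7.28 to 7.70. The ratio therefore does not decide against a clock that had shifted. A ratio under 0.5 was found in 702 probe sets, which may owe part of their 8 h change to clock time. The shared end of night arrays, a technical source of likeness, are argued against by the covariance of the changes. With separate arrays, A for 8 h and C for 24 h, it was 1.01 times that with shared arrays (0.522 against 0.517). This choice gave the highest of the 6 values possible with separate arrays, and the lowest was 0.48. Shared arrays without effects would give 0.0147. A biological effect of the longer darkness stays open and was not tested apart from these.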

How the results depend on the processing

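No called list, and none of the called genes in the 227 gene and comparison pairs below, changed direction under any alternative run. The genes named at 2 h and -2 h and in the closing observations are not among these pairs, and their values were not collected under the alternatives. Of 2882 alternative values for the named genes, 2764 kept direction and call and 118 lost the call, in 43 of 227 gene and comparison pairs; the block by letter lost 0 of them and, apart from cytosolic ribosomal proteins at 4 h and 48 h, changed no call of the first 11 lists. Unless the construction shows it (stricter thresholds, fewer probe sets or fewer arrays), the cause was not tested.

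At adjusted p under 0.01 the calls were 1950 at 4 h, 4166 at 8 h, 263 for 8 h against 4 h, 227 for 24 h against 8 h, 362 for 48 h against 24 h, 1 at -2 h, 35 at 2 h and 2198 at 6 h, with 1739 shared by 4 h and 8 h. With at least 2-fold change they were 1298, 2692, 3374 and 4773 at 4 h, 8 h, 24 h and 48 h, 416, 338 and 563 for the 3 steps, 2210 at 6 h and 3824 for the slope, over 10 h, with 1123, 2183 and 3080 shared by successive times. The replicate block gave 5960 at 4 h and 2459, 1523 and 2972 for the steps. Array weights gave 1391 for 8 h against 4 h, 645 for 48 h against 24 h and 8 at -2 h; the 2 time points alone gave 273 for 24 h against 8 h and 2 for 48 h against 24 h. At -2 h a second quantile normalization gave 1, the filter on dim probe sets 0, trend and robust settings 13, and leaving out both 48 h arrays (chosen after seeing the data) 8.

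Leaving out 1 array gave 1759 to 2930 calls at 4 h, 185 to 397 for 8 h against 4 h, 157 to 261 for 24 h against 8 h and 346 to 1739 for 48 h against 24 h.

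Of the 11 lists, 5, 6, 7 and 8 were called at 4 h, 8 h, 24 h and 48 h and 4, 2 and 7 in the 3 steps. With an estimated correlation these became 0, 0, 1 and 3, then 0 for 8 h against 4 h, 2 for 24 h against 8 h and 1 for 48 h against 24 h. With fry they were 10 at 8 h and 2 for 8 h against 4 h, and with the filter on dim probe sets 5 at 24 h, 5 at 48 h and 2 for 8 h against 4 h. That filter left 9 lists testable, without starch synthesis, called at 24 h and 48 h, and root markers. With fewer genes tested it ended the calls of tetrapyrrole synthesis and cytosolic ribosomal proteins at 8 h, fatty acid beta-oxidation at 24 h and cell wall growth and ribosomal proteins at 48 h, and of photosynthesis and tetrapyrrole synthesis between 4 h and 8 h, and of ribosomal proteins between 24 h and 48 h. For 24 h against 8 h, leaving out both 48 h arrays gave 4 and leaving out 1 array 2 to 4. A signal near background limits dim probe sets; the array files used here hold no background estimate.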

Other observations

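The gene families in this part were not among the lists fixed at the start, their members named here were chosen after their values were seen, and of the tests below those of poly(A) priming and of median centring were chosen after the result was seen. Subunits and assembly factors of the plastid NDH complex, which carries cyclic electron flow around photosystem I, fell in 5, 6, 7 and 7 of 8 genes at 4 h, 8 h, 24 h and 48 h (6, 7, 7 and 7 adjusted over the list alone). NdhN was at -3.58 ± 0.17 at 24 h and -4.36 ± 0.17 at 48 h, NdhL at -2.62 ± 0.15 and -3.90 ± 0.15, and NdhS rose by 0.62 ± 0.10 and 0.85 ± 0.10. Camera gave adjusted p = 5.52e-04, 4.24e-04, 1.96e-04 and 4.71e-04 at the 4 times, and adjusted p = 0.263, 0.276, 0.276 and 0.325 with an estimated correlation. Trichome birefringence-like proteins, which acetylate cell wall polysaccharides, fell in 8 of 22 cases at 8 h and 7 at 48 h, the same adjusted over the list alone (adjusted p = 0.0225 and 0.0222; adjusted p = 0.276 and 0.325 with an estimated correlation, and 0.117 without 48 h array C and 0.0565 without the dimmest probe sets at 48 h), with TBL45 at -2.68 ± 0.21 and -4.14 ± 0.21.

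Serine carboxypeptidase-like proteins fell in 7 of 29 cases at 4 h, also 7 adjusted over the list alone, with scpl46 at -1.56 ± 0.11 and scpl35 at -1.11 ± 0.17. The carboxypeptidase family had adjusted p = 0.00982 by camera, and adjusted p = 0.263 with an estimated correlation. WRKY transcription factors rose in 3 of 6 cases at 4 h (4 adjusted over the list alone; adjusted p = 0.00107, and adjusted p = 0.209 with an estimated correlation); 3 of the 6 genes, WRKY22, WRKY53 and WRKY6, are also in the leaf senescence list. UDP-glycosyltransferases rose in 6 of 47 cases at 4 h and fell in 4 (8 and 4 adjusted over the list alone). The list of UDP-glycosyltransferases was called there (adjusted p = 0.0468; adjusted p = 0.403 with an estimated correlation), but not without the dimmest probe sets (0.187), with letters as a block (0.118), with both 48 h arrays left out (0.0508), or without end of night array C (0.147) or 4 h array A (0.0504) or B (0.0751). From 24 h to 48 h 4 rose and 0 fell, the same adjusted over the list alone (adjusted p = 0.0395; adjusted p = 0.527 with an estimated correlation), a call lost without the dimmest probe sets (0.394), with the block (0.0734) and without 24 h array C (0.336) or 48 h array C (0.283). At 48 h they rose in 16 of 47 cases and fell in 4 (16 and 6 adjusted over the list alone), and the list gave adjusted p = 0.09, and adjusted p = 0.503 with an estimated correlation. Among them UGT73B1 rose by 3.52 ± 0.17, while the flavonol glycosyltransferases UGT78D1 and UGT78D2 fell (-2.56 ± 0.21 and -2.75 ± 0.20). Of the 25 added lists camera called 5 at 4 h, 3 at 8 h, 1 at 24 h and 3 at 48 h, and 0 at these times with an estimated correlation.

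Transcripts of the plastid genome fell at 48 h in 25 of 69 cases (16 adjusted over the list alone). The list had a median of -0.82 and adjusted p = 2.35e-04 by camera, and adjusted p = 0.434 with an estimated correlation. A single odd array at 48 h as the whole cause is argued against by the medians of both arrays, -0.999 on B and -0.417 on C. The end of night arrays had 0.0193 to 0.0661 and the arrays of the other times -0.11 to 0.263. C passed the limit set beforehand only narrowly. The shift was larger on B, which also had the low 25S rRNA control, so the size of the list's change leans on B. Poorer priming of transcripts without long poly(A) tails is argued against by the mitochondrion-encoded transcripts, with a median of 0.33 and 7 rises against 1 fall among 16 (7 and 1 adjusted over the list alone, camera adjusted p = 0.164), nad5 at 2.21 ± 0.36, and scaling between arrays by a median of -0.734 after median centring. A lower level of plastid transcripts in the plants had no test of its own and stays open. RNA degradation that differs between the organelles also remains open and was not tested; the actin 3' minus 5' difference was 2.02 on 48 h B and 1.35 on 48 h C for 1 control and 2.44 and 2.32 for the other, and for ubiquitin 1.08 and 0.78, and 1.92 and 1.52.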
